A study of Gallus gallus with 8 samples.

How the data were processed

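Whole blood and PBMC of the same 4 male broilers were compared on 8 single-colour Agilent arrays of a custom chicken design, 4 per group. Per the labels' protocols, PBMC were separated on a Ficoll gradient, RNA was extracted with TRIzol, and Cy3-labelled cRNA was hybridised. Groups and replicate numbers come from the sample labels, and the design text states that both samples came from the same birds. All arrays lay on 1 slide with 1 scan date.

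The spot intensities were background-subtracted and spatially detrended within each array by Agilent Feature Extraction before they were deposited, per the file headers, and were not normalized between arrays. The headers name version 10.7.3.1 of that software and the submitters' processing notes version 10.7.1.1. The deposited table of processed values holds log2 values of 46154 features. Set against the arrays, each column equalled the log2 of the spot's median pixel signal minus 1 constant per array, with no background correction, and each column's median was 0. The filter behind that table is not given in the sources used here. It holds the 35936 features that were well above background on all 8 arrays and none that was above background on no array. No column of per-sample values was left unused (0).

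From the array files, control spots (1319 per array) and spots marked as outliers by the scanner software were left out, leaving up to 61350 spots of 60539 probes. The main values are log2 of the processed signal minus the array's 75th percentile of it, with spots of the same probe averaged. No probe was saturated on any array, where a probe counted as saturated if at least 0.5 of its spots were. A gene with several probes was represented by the probe with the highest mean over the 8 arrays. A feature was tested if its probe was well above background on all 4 arrays of at least 1 group, which kept 33760 of 49527 features; 92 of these lacked a value on some array. The signal over background, with 664 to 846 as the 75th percentile, sets how far down levels can be read.

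Probes were named through a table of RefSeq genes (assembly GRCg7b), which differs from the build named in the headers (galGal3), so no coordinates are given. Of 12933 probes with a RefSeq accession, 10812 matched, 5139 probes were named by the gene number and 2882 by the symbol within the probe name, and 17397 probes with an Ensembl transcript and 22188 with other identifiers stayed unnamed. In all 18833 probes (31.1%) carried 7821 gene names. Unnamed probes were tested as themselves. Among 3806 genes with several detected probes, 394 had probes of opposite sign and 83 had probes that passed the test in opposite directions. SLC4A1, GATA1, CSF1R, ITGA2B and GP9, which were to be named whatever their result, were not matched to a probe and were not analysed here.

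Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all tested features and a threshold of 0.05. SE is the standard error from that fit, and SD the standard deviation over the 4 arrays of a group. The 24 gene lists were fixed before the data were examined and tested with limma's camera (preset correlation 0.01, adjusted over the lists), with camera under a correlation estimated per list, and with fry. Values per array were compared with exact two-sided permutation tests over the 70 assignments of 8 arrays, and with sign flips within birds. The globin share is the part of the summed signal that falls on probes of the globin list.

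The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 12 with the largest change in each direction among named genes past the threshold, well above background on at least 1 array of each group and changed the same way in all 4 birds. It adds the 4 largest lower bounds per direction, up to 4 members of each list with the largest change past the threshold, and a set named whatever their result (ALAS2, CD3E, CD4, CD8A, CD79B, CSF3R, TLR4, CATHL2, GZMA, BLB2, B2M, ACTB and GAPDH among those matched). Some genes that the rule takes are not reported here. Through synonyms in the reference, ALAS2 was matched to ALAS1 and CATHL2 to CATH2. Whether the ALAS1 probe detects ALAS2 was not tested. A lower bound was given where no array of 1 group was well above background. It is the bright group's mean against, for the dim group, the mean over arrays of the higher of the probe's own signal and the lowest signal among probes well above background.

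The replicate numbers pair the samples, since the same birds gave both. Deviations from the group means correlated within birds at 0.435, 0.478, 0.359 and 0.417, against at most 0.0439 between birds. The fit without the block was kept as the main one, as fixed beforehand, with the bird as a block among the alternatives. Other alternatives were background correction by normexp (offset 50, on the median signal, since the mean signal named in the plan is not a column used here), quantile, median and cyclic loess scaling, the 75th percentile over probes above background, other filters on dim probes, other rules for several probes of a gene, another detection call, slide row as a block or each row alone, eBayes with trend and robust, array weights, other thresholds, the authors' processed values, and leaving out each array or bird. Scaling to the spike-in probes and a test of named genes only were added after the data were seen.

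The fit was tested on simulated data for this comparison with 33760 features. With 50 features each changed by 0.5, 1, 2 and 4 (log2), 0%, 34%, 84% and 96% of them were recovered, with 9 false calls. With 5002 to 5116 features changed by each of these sizes, 49.5%, 84.1%, 97.5% and 99.7% were recovered, and 1.95% of the calls were false. A simulated list of 20 genes shifted by 1 was called and 0 of 24 unchanged lists were. The simulated genes varied independently, and most features were unchanged in the simulation that held the lists. In the data the estimated correlation reached 0.834 in the globin list. The simulated lists therefore do not show how often camera calls lists of correlated genes rightly or falsely in these data.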

Results

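Gene expression was measured in whole blood and in peripheral blood mononuclear cells (PBMC) of the same 4 male broiler chickens, aged 9 weeks, with 1 single-colour microarray per sample. Chicken red cells and thrombocytes keep their nucleus, so whole blood RNA comes from red cells, thrombocytes and white cells together. The PBMC had been separated from the blood on a density gradient (Ficoll), a step that keeps light cells such as lymphocytes and monocytes and lets most red cells sink. The comparison asked how the transcriptomes of these sample types differ. Each group held 4 arrays, and replicate numbers identify the birds. Levels are log2 signals relative to the 75th percentile of the array, and differences are PBMC minus whole blood. Per array, 68.4 ± 2.82% of the probes (SD, n = 4) were well above background in whole blood and 70.1 ± 2.41% in PBMC (exact two-sided permutation test, p = 0.429, higher in PBMC in 2 of 4 birds). The 75th percentile of the signal lay between 664 and 846 on the 8 arrays. The number of arrays limits the precision of every value. Where another background correction (normexp), the authors' values (no background correction), another scaling, another rule for probes, a slide row or a left-out array moved a named value by over 1.5-fold, that value is given.

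Isolation of PBMC went with lower levels of red cell genes and higher levels of lymphocyte, monocyte and thrombocyte genes, and most of the transcriptome differed between the sample types. Of 33760 features tested (5994 named genes and 27766 probes without a name here), 26711 differed (79.1%; limma, Benjamini-Hochberg adjusted p under 0.05), 13413 higher in PBMC and 13298 higher in whole blood. Among the named genes 4777 differed, 2528 of them higher in PBMC. At least 2-fold differences were found for 20771 features, 11086 higher in PBMC. Among the features that differed, 26275 went the same way in all 4 birds. Correlations between arrays across features, which are not independent replicates, were 0.971 to 0.983 within whole blood, 0.973 to 0.979 within PBMC and 0.760 to 0.803 between them. All arrays shared 1 slide. Its columns held whole blood or PBMC only, so column and sample type cannot be told apart. Its rows held both sample types, but row 1 held birds 2 and 4 and row 2 held birds 1 and 3. A slide row given here or below therefore cannot be told apart from its pair of birds. With the row as a block 27158 features differed, with 23525 in row 1 alone and 23466 in row 2 alone. All 13 gene lists called below kept their call with the row as a block and in each row alone.

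**Figure D1:**
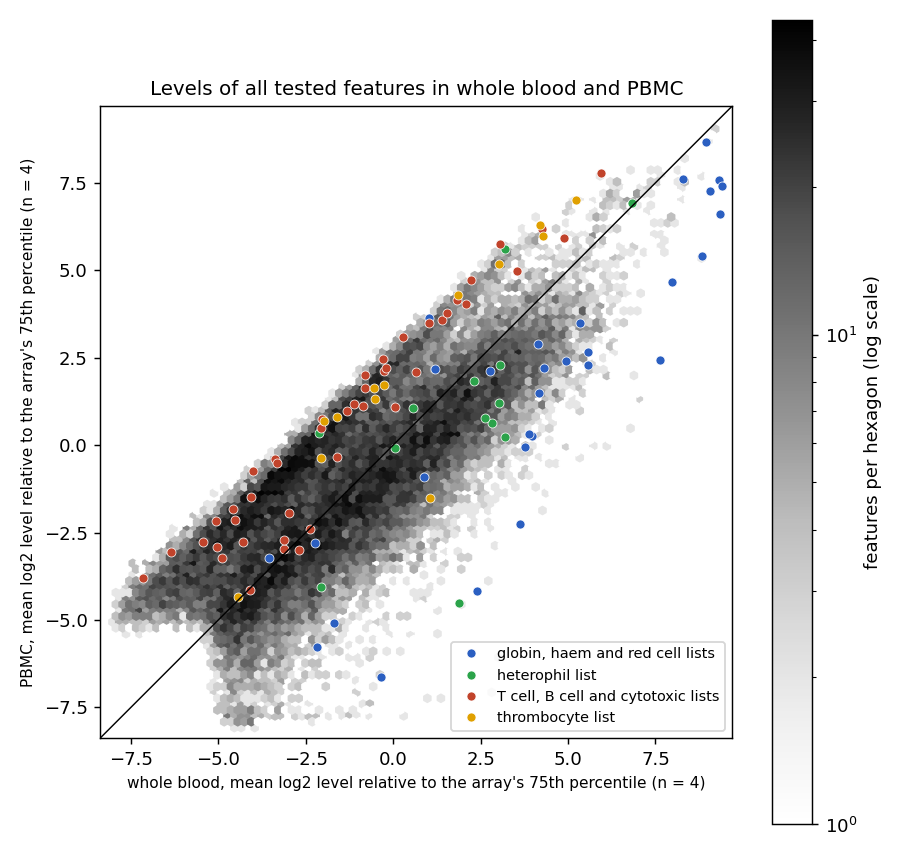
Mean log2 level of the 33760 tested features in whole blood (horizontal axis) and PBMC (vertical axis), each relative to the array's 75th percentile, n = 4 arrays per group; grey hexagons count features, coloured points are members of fixed gene lists, and the black line marks equal levels. Most lymphocyte and thrombocyte genes lie above the line and most red cell genes below it, down to -6.58 (log2) for SLC25A37; MPP1 (2.61), FTL (0.98) and GFI1B (-2.57) are among the exceptions.

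The 12 named genes with the largest rise in PBMC in the main values, among those measured in both groups, differed by 3.28 to 3.59 on the log2 scale. They included BCL2A1, which protects cells from apoptosis (3.55 ± 0.27, log2 difference ± SE, adjusted p = 2.76e-06), the costimulatory molecule CD86 (3.35 ± 0.52, adjusted p = 2.61e-04), the immunoglobulin joining chain JCHAIN (3.31 ± 0.44, adjusted p = 1.02e-04), the matrix proteoglycan VCAN (3.31 ± 0.45, adjusted p = 1.10e-04), the granzyme GZMK (3.29 ± 0.56, adjusted p = 5.02e-04) and the interleukin 18 receptor chain IL18R1 (3.29 ± 0.27, adjusted p = 4.92e-06). The others were PPP1R1C, CMC1, RNASET2, SLC24A4, RNASEH2B and CALCRL. In whole blood some of these were dim: PPP1R1C and CD86 were well above background on 2 of 4 arrays there, and JCHAIN on 1. Sizes and order depend on the background correction. With normexp and in the authors' values, PPP1R1C differed by 1.34 and 1.53, BCL2A1 by 1.67 and 1.85, CMC1 by 1.83 and 2.02, CD86 by 0.99 and 1.16, and JCHAIN by 1.08 and 1.34. RNASET2 differed by 2.31 and 2.45 there, SLC24A4 by 1.93 and 2.11, GZMK by 2.41 and 2.48, IL18R1 by 2.12 and 2.21, and CALCRL by 2.56 and 2.59. CD86 differed by 1.95 with the mean of its probes. Here and below, that mean takes in probes that were not detected, and CD86 had 1 detected probe. In slide rows 1 and 2 alone, PPP1R1C differed by 2.80 and 4.37 and CMC1 by 2.61 and 4.47. Without whole blood replicate 3, PPP1R1C differed by 2.89 and CMC1 by 2.67 (2.76 without bird 3).

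The 12 with the largest rise in whole blood in the main values differed by 63.0-fold to 152-fold. PHOSPHO1, a phosphatase of phosphocholine, differed by -7.25 ± 0.19 (adjusted p = 6.72e-08), the keratin KRT7 by -7.03 ± 0.65 (adjusted p = 9.17e-06) and SLC22A23 by -6.71 ± 0.24 (adjusted p = 1.34e-07). Mitoferrin, SLC25A37, which carries iron into mitochondria, differed by -6.58 ± 0.23, the gelatinase MMP9 by -6.40 ± 0.59, the paraoxonase gene named PON1 here by -6.36 ± 0.44 and the lens protein gene CRYBB3 by -6.12 ± 0.21. The probe used for PON1 carries the symbol PON2 in its name. FAM173B, ARRDC2, BBOF1, IQUB and IFI27L2 lay between -5.98 and -6.43. In PBMC, SLC22A23 and BBOF1 were well above background on 1 of 4 arrays, IQUB on 2 and MMP9 on 3. With normexp and in the authors' values, SLC22A23 differed by -3.98 and -4.56, BBOF1 by -3.62 and -4.14, IQUB by -3.70 and -4.21, and MMP9 by -4.79 and -5.27. KRT7 differed by -5.86 and -6.27 there, PHOSPHO1 by -5.58 and -6.09, SLC25A37 by -5.14 and -5.63, and FAM173B by -5.23 and -5.67, so the order depends on the background correction too. With the mean of a gene's probes, KRT7 differed by -6.29 and SLC22A23, which had 1 detected probe, by -4.89. In slide rows 1 and 2 alone, IFI27L2 differed by -4.73 and -7.22. KRT7 differed by -7.67 without whole blood replicate 2, IQUB by -5.24 without PBMC replicate 3, and IFI27L2 by -6.66 without PBMC replicate 2 (-6.65 without bird 2). ARRDC2 stood at 6.81 ± 0.11 (SD, n = 4) in whole blood and 0.41 ± 0.52 in PBMC.

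Some genes were not well above background on any array of 1 group, so only a lower bound of the ratio can be given. On each array of the dimmer group, the bound uses the higher of the probe's own signal and the lowest signal counted as well above background. WNK4, a kinase that regulates ion transport, was at least 604-fold higher in whole blood (adjusted p = 9.83e-09), HMGA2 at least 155-fold, CRABP1 at least 101.5-fold and SEMA3D at least 100.2-fold. In the other direction the bounds were smaller, at least 9.73-fold for STX18, 7.89-fold for the phosphatidate phosphatase LPIN1, 7.18-fold for the glucosylceramide synthase UGCG and 7.04-fold for interferon gamma, IFNG (adjusted p = 8.07e-07). These bounds hold for the probe used and the main background correction only. Another probe of the same gene differed by -6.52 for HMGA2, -6.07 for CRABP1, -6.20 for SEMA3D, 2.18 for LPIN1 and 2.48 for IFNG, each short of the bound. With the mean of a gene's probes, HMGA2 differed by -7.34, SEMA3D by -7.02, LPIN1 by 2.91 and IFNG by 2.58. With normexp, which shrinks differences of dim genes by its offset, the log2 differences were -6.43 for WNK4, -4.42 for HMGA2, -3.82 for CRABP1, -4.06 for SEMA3D, 0.97 for STX18, 0.80 for LPIN1, 0.71 for UGCG and 0.66 for IFNG. In the authors' values they were -7.09, -5.05, -4.50, -4.71, 1.15, 1.02, 0.94 and 0.82. All 8 kept their call in both. Of the 127 genes picked by the naming rule, 42 were smaller by over 1.5-fold with normexp and 39 in the authors' values. By the probe used for each gene, 84 named genes were well above background on all whole blood arrays and on no PBMC array, and 87 the other way round.

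Red cell genes were lower in PBMC. All 7 tested globin genes fell, with a median difference of -2.74 (camera, adjusted p = 0.00591; adjusted p = 0.445 with an estimated correlation). The median was -1.90 with cyclic loess, -2.03 with normexp, -2.05 in slide row 1 alone and -3.43 in slide row 2 alone, with the call kept in each. HBAD, an alpha-type globin, went from 9.36 ± 0.16 (SD, n = 4) in whole blood to 6.62 ± 0.88 in PBMC, HBE differed by -3.43 ± 0.25 (SE), HBBR by -3.29 ± 0.28 and HBZ by -3.59 ± 0.26, the last of them well above background on 1 of 4 PBMC arrays. HBAD differed by -1.90 with cyclic loess and by -2.05 and -3.43 in slide rows 1 and 2 alone. HBE differed by -2.65 with cyclic loess and -2.79 with quantile normalization, HBBR by -2.57 with cyclic loess, and HBZ by -1.53 with normexp, -2.03 in the authors' values and -4.24 with the mean of its probes. Globin genes resemble each other in sequence, and probes of the same gene differed in size, from -1.42 to -7.32 for the gene named HBE1 here, so single globin values are uncertain. The globin genes took 3.74 ± 0.30% of the summed signal in whole blood and 1.12 ± 0.37% in PBMC (exact two-sided permutation test, p = 0.0286, the smallest that 70 splits allow; 0.0714 after adjustment over 5 such measures). The share was lower in PBMC in 4 of 4 birds, and an exact test by sign flips within birds, which allows for the pairing, gave p = 0.125, the smallest that 4 birds allow.

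Of 11 tested genes of haem synthesis and iron handling, 8 were lower in PBMC and 1 was higher (9 lower when adjusted over the list alone), at a median of -1.86 (camera, adjusted p = 0.00523; adjusted p = 0.342 with an estimated correlation). The transferrin receptor TFRC fell from 3.63 ± 0.15 (SD, n = 4) to -2.25 ± 0.20 (adjusted p = 6.72e-08). ABCB6, a porphyrin transporter, differed by -3.40 ± 0.16 (SE; -1.67 with normexp and -2.08 in the authors' values), and GLRX5, which serves iron-sulfur cluster assembly, by -2.92 ± 0.14. The member that was higher in PBMC was the ferritin light chain FTL (0.98 ± 0.24), singled out after its value was seen. For the gene named ALAS1 here the reference lists ALAS2 as a synonym, and whether the probe detects ALAS2 was not tested. ALAS1 differed by -0.66 ± 0.16 (adjusted p = 0.00409). Its call ended with quantile normalization (-0.26, adjusted p = 0.163), cyclic loess (-0.33, adjusted p = 0.0897) and in slide row 2 alone (-0.43, adjusted p = 0.146).

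Of 12 tested genes of the red cell membrane, its enzymes and its transcription factors, 9 were lower in PBMC, 1 was higher and 2 did not pass, at a median of -2.92 (camera, adjusted p = 0.0221; adjusted p = 0.445 with an estimated correlation). The call ended with cyclic loess (median -2.46, adjusted p = 0.0537) and over features above background on all 8 arrays (median -2.55, adjusted p = 0.0551), and the median was -2.33 with the mean of a gene's probes (adjusted p = 0.0312). Carbonic anhydrase CA2 fell from 7.63 ± 0.49 (SD, n = 4) to 2.43 ± 0.56 (-4.60 with cyclic loess), the membrane skeleton protein EPB41 differed by -3.84 ± 0.20 (SE) and the bisphosphoglycerate mutase BPGM by -3.69 ± 0.28. XK, a membrane protein linked to the Kell antigen, was not well above background on any PBMC array and at least 55.4-fold higher in whole blood. Its log2 difference was -3.40 with normexp and -3.92 in the authors' values, below that bound, -5.39 and -7.19 in slide rows 1 and 2 alone, and -5.66 without bird 3. MPP1, a membrane scaffold protein, was the member that rose (2.61 ± 0.25), named after its value was seen. Of 9 tested autophagy and ubiquitin genes of red cell maturation, 6 were lower in PBMC and 2 higher, without a call for the list (median -1.33, adjusted p = 0.0982). The autophagy genes ATG9A (-3.00 ± 0.12) and ULK1 (-2.85 ± 0.22; -2.03 with normexp), the mitophagy receptor BNIP3L (-1.59 ± 0.15) and UBAC1 (-1.35 ± 0.22) were among those that fell.

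**Figure D2:**
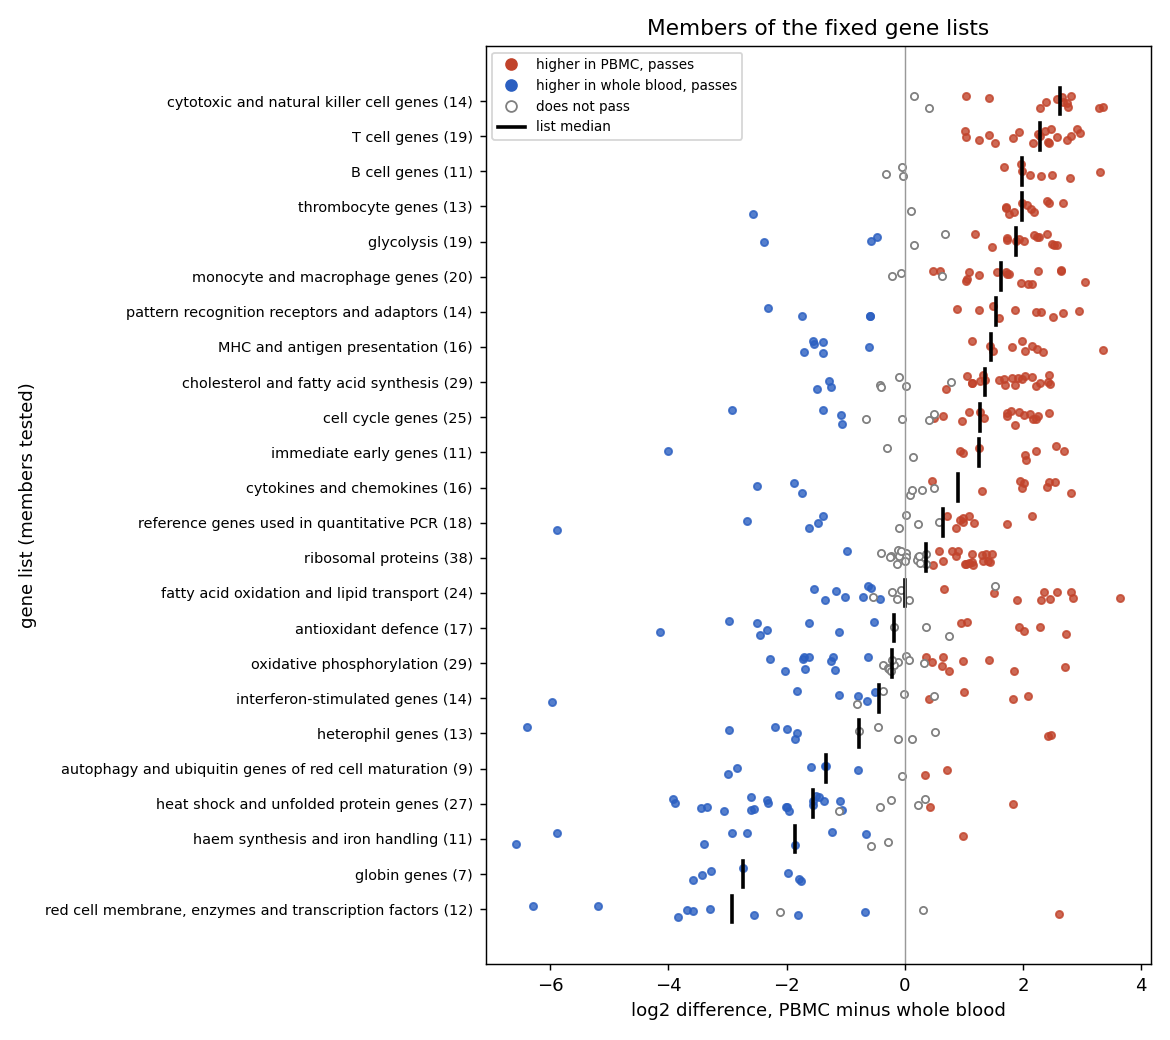
Log2 difference, PBMC minus whole blood (horizontal axis), of each tested member of the 24 fixed gene lists (vertical axis, members tested in parentheses, ordered by median); red and blue points pass the test, open points do not, and black bars are list medians. The T cell list lies wholly above 0 (median 2.28), the globin list wholly below it (median -2.74), and the heterophil list spans both sides.

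Lymphocyte genes were higher in PBMC. All 19 tested T cell genes rose, at a median of 2.28 (camera, adjusted p = 1.17e-05; adjusted p = 0.342 with an estimated correlation). The T cell receptor signalling chain CD3E went from 4.24 ± 0.18 (SD, n = 4) to 6.17 ± 0.17, CD4 differed by 2.82 ± 0.25 (SE), CD8A by 1.02 ± 0.15, the checkpoint receptor CTLA4 by 2.97 ± 0.26, the costimulator ICOS by 2.92 ± 0.52 (2.33 without whole blood replicate 1) and the interleukin 7 receptor IL7R by 2.74 ± 0.14. With normexp and in the authors' values, ICOS differed by 1.12 and 1.16 and CTLA4 by 2.26 and 2.32. CD8A differed by 1.82 with the mean of its probes and CD3E by 2.55 with cyclic loess. Of 11 tested B cell genes, 8 rose and 3 did not pass, at a median of 1.99 (camera, adjusted p = 0.0214; adjusted p = 0.4325 with an estimated correlation), among them the antigen receptor chain CD79B (2.49 ± 0.28), the transcription factor PAX5 (2.79 ± 0.37; 2.05 with normexp, 2.14 in the authors' values, 2.07 with the mean of its probes), JCHAIN and the gene named SH2D6 here, for which the reference lists BLNK as a synonym (2.30 ± 0.18). Of 14 cytotoxic and natural killer cell genes, 12 rose (13 when adjusted over the list alone) and none fell, at a median of 2.62 (camera, adjusted p = 0.00259; adjusted p = 0.4325 with an estimated correlation). Examples are the granzyme GZMA (2.81 ± 0.41), the chemokine XCL1 (2.76 ± 0.17), IL18R1 and IFNG. The B cell and cytotoxic medians were 1.08 and 1.44 with normexp and 1.34 and 1.43 in the authors' values, and both lists kept their call.

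Monocyte and thrombocyte genes were also higher in PBMC. Of 20 monocyte and macrophage genes, 17 rose and 3 did not pass, at a median of 1.64 (camera, adjusted p = 0.00363; adjusted p = 0.445 with an estimated correlation). The median was 1.08 with normexp and 0.99 in the authors' values, with the call kept. The chemokine receptor CCR2 differed by 3.05 ± 0.36 (1.93 with normexp and 2.04 in the authors' values), LY86 by 2.64 ± 0.25 and the lectin LGALS3 by 2.25 ± 0.38. The endotoxin receptor TLR4 differed by 1.25 ± 0.32 (adjusted p = 0.00537), a call that ended in slide row 1 alone (1.12, adjusted p = 0.0537) and row 2 alone (1.39, adjusted p = 0.0536). Of 13 thrombocyte genes, 11 rose, 1 fell and 1 did not pass, at a median of 1.98 (camera, adjusted p = 0.00591; adjusted p = 0.342 with an estimated correlation). The laminin-binding integrin chain ITGA6 differed by 2.67 ± 0.20, pleckstrin, PLEK, by 2.44 ± 0.19 and the ATP receptor P2RX1 by 2.40 ± 0.36. GFI1B, a transcription factor of both red cell and thrombocyte precursors, was the member that fell (-2.57 ± 0.24).

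Genes of heterophils, the avian counterpart of neutrophils, were not called by camera, which sets a list against all other genes (median -0.78, adjusted p = 0.411). By fry, which asks only whether the list moved, they were called (adjusted p = 0.0324). Fry called 23 of the 24 lists, however, among them fatty acid oxidation with a median of -0.0031, so its call sets heterophil genes little apart. The heterophil median was below 0 in 4 of 4 birds. Of 13 tested, 6 were lower in PBMC, 2 were higher and 5 did not pass. MMP9 fell from 1.87 ± 0.72 (SD, n = 4) to -4.52 ± 1.21, and was well above background on 3 of 4 PBMC arrays. The gene named S100A12 here, for which the reference lists S100A9, differed by -2.98 ± 0.90 (SE, adjusted p = 0.0128), without a call when bird 4 was left out (-2.69, adjusted p = 0.0698) or in slide row 2 alone (-3.03, adjusted p = 0.166). It differed by -2.09 without PBMC replicate 1 and by -3.68 without PBMC replicate 3. The goose-type lysozyme LYGL (2.48 ± 0.33) and the ribonuclease RSFR (2.43 ± 0.32) were the members that rose. The cathelicidin CATH2 (-0.46 ± 0.45, adjusted p = 0.363, lower in PBMC in 3 of 4 birds) and the receptor CSF3R (0.51 ± 0.47, adjusted p = 0.330, higher in PBMC in 2 of 4 birds) did not pass. Without whole blood replicate 4, CATH2 passed (-0.89, adjusted p = 0.0331).

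**Figure D3:**
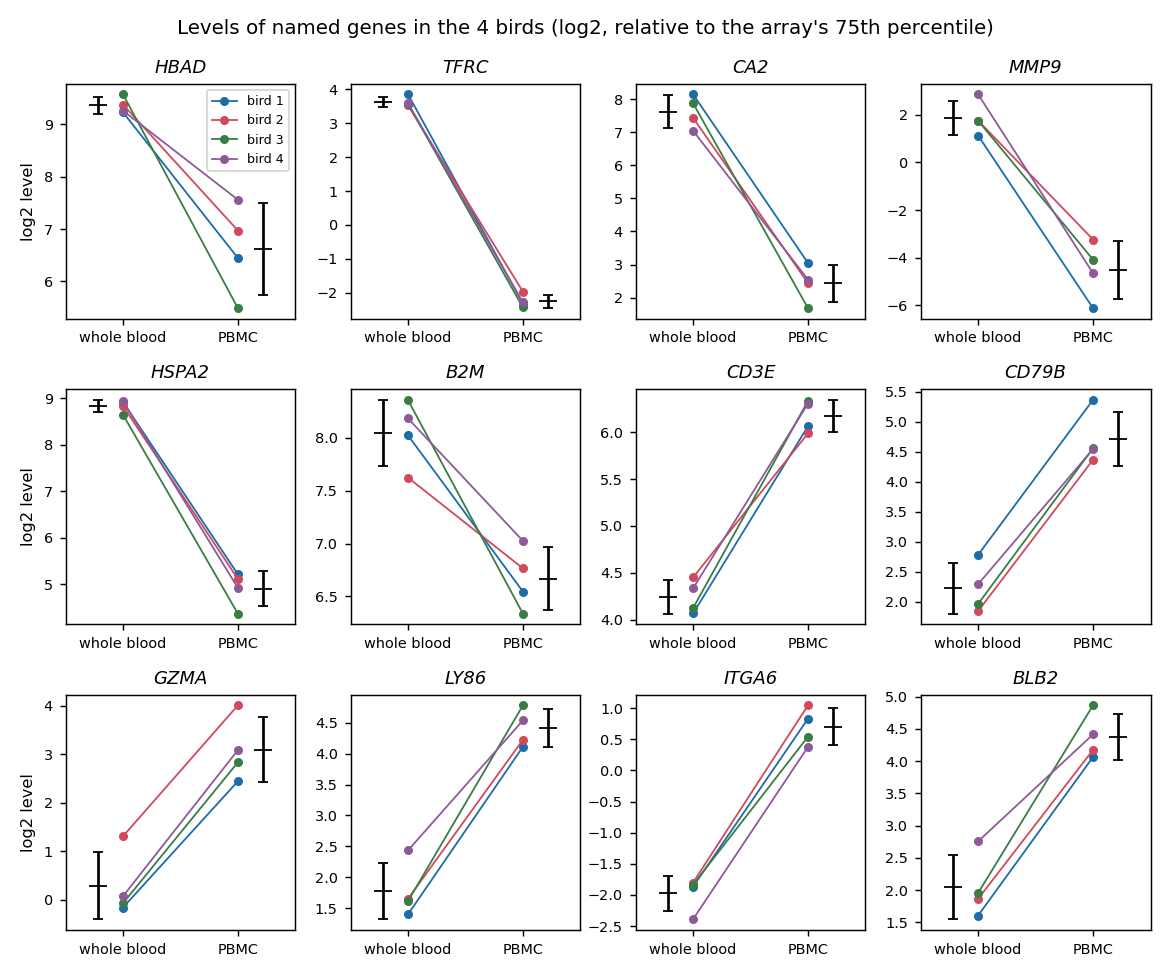
Log2 level relative to the array's 75th percentile (vertical axes, which do not start at 0) of 12 genes in whole blood and PBMC; each coloured line joins the samples of 1 bird, and black marks give the group mean with its SD (n = 4). The top row and HSPA2 and B2M are lower in PBMC in all 4 birds, by -2.74 for HBAD and -1.38 for B2M, and the remaining genes are higher, by 1.93 for CD3E and 2.81 for GZMA.

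Genes of antigen presentation went both ways. All 16 tested differed, 10 higher in PBMC and 6 higher in whole blood, without a call for the list (median 1.46, camera, adjusted p = 0.411). The class II beta chains BLB1 (2.16 ± 0.29) and BLB2 (2.34 ± 0.27), which present peptides to helper T cells, the lipid-presenting CD1C (2.23 ± 0.24; 1.09 with normexp and 1.23 in the authors' values) and CD86 were higher in PBMC. Beta-2 microglobulin, B2M, the light chain of class I molecules, was higher in whole blood, at 8.05 ± 0.31 (SD, n = 4) against 6.67 ± 0.30 (adjusted p = 2.28e-04). So were the class I heavy chains BF1 (-1.55 ± 0.24, SE) and BF2 (-1.53 ± 0.21) and the peptide transporter chains TAP1 (-1.39 ± 0.20) and TAP2 (-1.70 ± 0.12), all named after their values were seen. The 6th was TAPBP (-0.60), also named after its value was seen, which ran from -0.91 to 0.17 over the scalings. B2M, BF1, BF2, TAP1 and TAP2 kept this direction under all scalings tried, with B2M down to -0.58, BF1 to -0.77, BF2 to -0.75 and TAP2 to -0.94 under the scaling nearest 0.

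Among 14 pattern recognition receptors and adaptors, 10 were higher in PBMC and 4 higher in whole blood (median 1.54, camera, adjusted p = 0.125). The RNA-sensing receptors TLR7 (2.94 ± 0.23) and TLR3 (2.50 ± 0.37) were higher in PBMC, as was NOD1, by at least 4.59-fold (a log2 difference of 0.39 with normexp and 0.53 in the authors' values, below that bound). The sensor gene DDX41 was higher in whole blood (-2.31 ± 0.18; -1.72 with normexp). Of 16 cytokines and chemokines tested, 9 were higher in PBMC (8 when adjusted over the list alone), 3 higher in whole blood and 4 did not pass (median 0.90, camera, adjusted p = 0.156; 0.43 with normexp, 0.41 in the authors' values, 0.12 without a filter on dim probes and 1.97 with every probe on its own). CCL5 (2.81 ± 0.43; 1.72 with normexp and 1.82 in the authors' values), IL16 (2.54 ± 0.20) and IL18 (at least 5.42-fold; log2 0.71 with normexp and 0.79 in the authors' values, below that bound) were higher in PBMC, and IL15, a growth factor of natural killer and memory T cells, was higher in whole blood (-2.49 ± 0.26). Of 14 interferon-stimulated genes, 4 were higher in PBMC, 6 higher in whole blood and 4 did not pass (median -0.44, camera, adjusted p = 0.514), with MX1 (2.09 ± 0.52) and IFITM5 (1.83 ± 0.32; 1.21 with the mean of its probes) on the PBMC side and IFI27L2 (-5.98 ± 0.69; -6.66 without PBMC replicate 2) and IRF1 (-1.82 ± 0.15; -1.18 with cyclic loess) on the other.

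Heat shock and unfolded protein genes were higher in whole blood. Of 27 tested, 20 fell in PBMC (22 when adjusted over the list alone) and 2 rose, at a median of -1.56 (camera, adjusted p = 5.28e-04; adjusted p = 0.342 with an estimated correlation). The chaperone HSPA2, the gene to which the reference assigns HSP70, went from 8.83 ± 0.13 (SD, n = 4) to 4.90 ± 0.38 (adjusted p = 5.04e-07). Its difference of -3.93 was -3.30 with quantile normalization, -3.17 with cyclic loess and -4.87 with the mean of its probes. The cochaperones DNAJA4 (-3.89 ± 0.22, SE), HSPH1 (-3.44 ± 0.20) and DNAJB9 (-3.34 ± 0.17) differed in the same direction. Of 11 immediate early genes, 8 were higher in PBMC and 1 was lower (median 1.25, camera, adjusted p = 0.0527). MYC (2.69 ± 0.19), KLF6 (2.56 ± 0.14) and CYR61 (2.22 ± 0.27) rose, and the transcription factor EGR1 fell from 2.28 ± 0.33 (SD, n = 4) to -1.72 ± 0.45. Of 17 antioxidant genes, 6 were higher in PBMC, 8 higher in whole blood and 3 did not pass (median -0.19, camera, adjusted p = 0.411). The glutathione synthesis enzyme GCLC (-4.14 ± 0.13, SE), the regulator NFE2L2 (-2.98 ± 0.19) and the superoxide dismutase SOD1 (-2.50 ± 0.19) were higher in whole blood and the glutathione transferase GSTA3 (2.72 ± 0.28) in PBMC.

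Genes of glycolysis and of lipid synthesis were higher in PBMC. Of 19 glycolysis genes, 14 rose and 3 fell, at a median of 1.88 (camera, adjusted p = 0.00355; adjusted p = 0.4325 with an estimated correlation), with enolase ENO1 at 2.53 ± 0.17, PDK1 at 2.57 ± 0.19, LDHB at 2.41 ± 0.20 and GPI at 2.49 ± 0.21. For GPI, 1 of 4 detected probes went the other way (-1.05), and the mean of its probes gave 1.36. Of 29 genes of cholesterol and fatty acid synthesis, 21 rose, 3 fell and 5 did not pass, at a median of 1.35 (camera, adjusted p = 0.00876; adjusted p = 0.448 with an estimated correlation), among them the sterol pathway enzymes SQLE (2.46 ± 0.26), LSS (2.42 ± 0.47) and CYP51A1 (2.29 ± 0.40; 1.60 with normexp and 1.62 in the authors' values). Genes of fatty acid oxidation and lipid transport went both ways (10 higher in PBMC, 8 higher in whole blood, 6 not passing; median -0.0031, while camera's direction was up, adjusted p = 0.411), with HADH (2.85 ± 0.18), FABP3 (2.81 ± 0.54) and ABCG1 (2.58 ± 0.20; 1.66 with normexp and 1.75 in the authors' values) higher in PBMC. So did the 29 oxidative phosphorylation genes, of which 9 were higher in PBMC and 10 higher in whole blood (median -0.21, camera, adjusted p = 0.422): ATP5I (2.71 ± 0.17) and COX5A (1.85 ± 0.14) against NDUFV3 (-2.29 ± 0.14) and NDUFA5 (-2.03 ± 0.18).

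Of 25 cell cycle genes, 17 rose, 4 fell and 4 did not pass, at a median of 1.27 (camera, adjusted p = 0.0180; adjusted p = 0.342 with an estimated correlation). The replication factor MCM3 (2.45 ± 0.26; 1.86 with normexp), CDC20 (2.26 ± 0.28), a cofactor that triggers anaphase, and the topoisomerase TOP2A (2.22 ± 0.18) rose, and the G1/S cyclin CCNE2 fell (-2.93 ± 0.49). Of 38 ribosomal protein genes, 18 rose, 1 fell and 19 did not pass, at a median of 0.36 (camera, adjusted p = 0.0132; adjusted p = 0.597 with an estimated correlation), led by RPL6 (1.48 ± 0.14), RPS3A (1.43 ± 0.15), RPL7A (1.41 ± 0.14) and RPS15 (1.37 ± 0.13). The call for this list ended with median scaling (median 0.05, adjusted p = 0.0934) and with scaling to the spike-in probes (0.22, adjusted p = 0.0801), the latter chosen after the data were seen. With cyclic loess the median was 1.14 (adjusted p = 1.10e-07), with RPL6 at 2.18, RPS3A at 2.19, RPL7A at 2.20 and RPS15 at 2.17. Among 18 genes often used as references in quantitative PCR, 9 were higher in PBMC, 5 higher in whole blood and 4 did not pass (median 0.64, camera, adjusted p = 0.467). GAPDH went from 5.29 ± 0.24 (SD, n = 4) to 7.01 ± 0.13, and ACTB from 7.30 ± 0.15 to 8.28 ± 0.05. PPIA differed by 2.15 ± 0.23 (SE) and TFRC by -5.89 ± 0.15; these 4 kept their direction under all scalings tried. With cyclic loess GAPDH differed by 2.43 and ACTB by 1.81, against 1.72 and 0.98 in the main values.

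The medians of the interferon-stimulated, oxidative phosphorylation, fatty acid oxidation and antioxidant lists, none of them called, changed sign under at least 1 other scaling. Adjustment over the list alone left the counts as given in 20 of the 24 lists, the exceptions being the haem, cytotoxic, cytokine and heat shock lists. Of the 24 lists, 13 were called in all by camera with its preset correlation of 0.01 and none with an estimated correlation (3 lists at an unadjusted p under 0.05), while fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, called 23. The spread between birds, as the mean absolute deviation from the group mean over tested features, was 0.27 ± 0.03 (log2, SD, n = 4) in whole blood and 0.25 ± 0.01 in PBMC (exact two-sided permutation test, p = 0.286, adjusted 0.476). Feature levels correlated between the group means at Pearson's r = 0.799 and Spearman's rho = 0.802 across features, which are not independent replicates.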

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

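The tests of explanations in this part were chosen after the results were seen. Each named gene and each list's mean was checked in whole blood and in PBMC. So were the percentage of probes well above background, the globin share and the spread between birds. Among these 308 groups of 4 samples, 16 had a sample far from the other 3, by a gap whose share of the group's range passed Dixon's critical value. Chance alone gives about 1 in 20, or 15.4. Each array was the distant sample 1 to 3 times. The values that follow are the gap's share of the range.

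In whole blood, ICOS had the widest gap (0.967), with replicate 1 at -6.83 and the others between -4.55 and -4.47. WNK4 (0.909) stood at 2.77 in replicate 2 against 2.92 to 2.94. ITGA6 (0.889) was lowest in replicate 4 at -2.39, and CD4 (0.869) was lowest in replicate 3 at -1.52. TLR7 (0.855) was highest in replicate 4 at -0.20, and the mean of the glycolysis list (0.853) was highest there at 1.53. GZMA (0.842) reached 1.31 in replicate 2 against -0.16 to 0.07, and PAX5 (0.831) reached -2.49 in replicate 1.

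In PBMC, HBBR (0.954) stood at 3.74 in replicate 3 against 4.95 to 5.01. TOP2A (0.914) was highest in replicate 2 at 0.61, GCLC (0.891) in replicate 1 at 2.04, CTLA4 (0.852) in replicate 4 at 0.31 and CMC1 (0.845) in replicate 4 at -0.60. TLR3 (0.8291) was lowest in replicate 3 at -1.07. The mean of the ribosomal protein list (0.888) was lowest in replicate 2 at 6.32, and that of the pattern recognition list (0.846) was lowest in replicate 1 at 0.57.

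Heterophil genes lay apart from the other white cell lists, with a median of -0.78 where those of the T cell, B cell, monocyte, cytotoxic and thrombocyte lists were 1.64 or higher. Loss of red cell RNA alone would raise lists whose genes red cells do not express. Lower in PBMC were 6 of 13 heterophil genes, against 13298 of 33760 tested features. Since other cells can express members of the list, this count does not exclude loss of red cell RNA as the whole cause. Of the 8 scalings, the 75th percentile over all probes or over those above background, median and spike-in scaling subtract a constant per array. These cannot change the gap between the heterophil median and the nearest of those lists (2.413 each). The gap was 1.841 with normexp, 1.821 with quantile normalization, 1.758 with cyclic loess and 1.932 in the authors' values, which argues against scaling as its cause. Heterophils may have stayed behind with the red cells in the gradient, a hypothesis that stays open because 2 members were higher in PBMC, because camera did not call the list and because other cells can express its members.

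Heat shock and unfolded protein genes were higher in whole blood, with a median of -1.56. The median nearest 0 over the 8 scalings was -1.326, which argues against the choice among these scalings as the cause. Red cells may be the source of these transcripts. The list median of -1.562 goes with that but cannot decide it, since no purified red cells were measured.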

How the results depend on the processing

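Scaling to the spike-in probes and the test of named genes only were chosen after the data were seen. Over the other settings the features that differed numbered 20771 (at least 2-fold) to 33446 (every probe on its own), and 25056 to 26379 with arrays or birds left out (12573 to 13305 higher in PBMC, 12473 to 13074 higher in whole blood; 13 to 14 lists). The share of these higher in PBMC lay between 42.9% (median scaling) and 56.2% (75th percentile over probes above background). The median difference over all features, 0.0029 in the main values, was -0.30 under median scaling, 0.24 under that percentile, -0.10 under cyclic loess, -0.15 in the authors' values and -0.13 under spike-in scaling. With named genes only, 4815 differed (2548 higher in PBMC, 2267 higher in whole blood), since fewer features were tested. With the replicate block, 27766 differed (26544 shared), and the globin share (-2.6185) had p = 0.125 by exact sign flips, the smallest that 4 birds allow; the block changed no call of a list or named gene. The share ranged from -2.76 to -2.45 with an array left out (exact permutation p = 0.0286 each time). The percentage of probes above background differed by 0.396 to 2.85. The spread between birds, which was not called, ranged from -0.038125 to 0.012354 and turned positive without whole blood replicate 1 (0.0057639) or 4 (0.012354). Deviations from a group's own mean shrink with fewer arrays. Leaving out any whole blood array thus raises this difference by itself, and leaving out any PBMC array lowers it. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05) and fry 23, against 13. Reversed were the interferon-stimulated list under quantile normalization (0.002309) and cyclic loess (-0.05623, where the test's direction turned), and oxidative phosphorylation (0.2363 and 0.1844); neither was called, and the cause was not tested. The immediate early list gained a call under 8 settings (adjusted p 0.0125 to 0.0481), pattern recognition under cyclic loess (0.0471) and every probe (0.0168), and autophagy without a filter (0.0453) and with every probe (0.0106). Of the named genes, 3776 comparisons with an alternative kept direction and call, 7 lost and 2 gained a call (CATH2 without whole blood replicate 4, or without bird 4, -0.62, adjusted p = 0.0384), and 0 reversed. Leaving out saturated spots was not run, since no probe was counted as saturated. Signal near background limits low levels.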

Other observations

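The families in the next paragraphs and the tests in this part were chosen after the results were seen, except the test of scaling on the reach of rises and falls, which was written before. None of the 12 families was called with an estimated correlation. All 11 tested genes with integrin symbols rose, at a median of 2.15 (camera, adjusted p = 0.00209 over 12 such families; adjusted p = 0.0918 with an estimated correlation). ITGB1BP3 and ITGB3BP among them are named for binding integrins and are not integrin chains. The chains ITGA1 (2.98 ± 0.16, SE), ITGA4 (2.28 ± 0.28) and ITGB2 (2.01 ± 0.17), through which leukocytes adhere, are examples. Of 16 actin genes 12 rose and 2 fell, at a median of 1.64 (adjusted p = 0.00577; adjusted p = 0.185 with an estimated correlation), among them TMSB4X (2.15 ± 0.14; up to 2.84 over the scalings), which binds actin monomers, and LCP1 (2.06 ± 0.17), which bundles filaments. In the protein kinase C family 5 of 6 rose (median 2.34, adjusted p = 0.0286; adjusted p = 0.185 with an estimated correlation) and PRKCI fell (-0.80 ± 0.20). Of 17 histone genes 14 rose and 3 fell (median 1.64, adjusted p = 0.0336; adjusted p = 0.470 with an estimated correlation), the latter H3F3C, H2AFZ and H1F0, the last of which reached 0.16 under another scaling.

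The other families that camera called with its preset correlation had more members that fell in PBMC than rose. Of 27 genes with proteasome symbols, 21 fell and 4 rose, at a median of -0.97 (camera, adjusted p = 0.00513; adjusted p = 0.308 with an estimated correlation), among them PSMC3 (-2.50 ± 0.12), with PSMD14 (2.00 ± 0.14) the other way. PSMG1, PSMG3, PSMG4, PSMD5 and PSMD9 among the 27 serve assembly and PSMF1 inhibits, so they are not subunits. Of 21 ubiquitin-conjugating enzymes 16 fell and 3 rose (median -1.04, adjusted p = 0.00513; adjusted p = 0.266 with an estimated correlation), including UBE2R2 (-3.90 ± 0.13) and UBE2D2 (-3.12 ± 0.16). Splicing factors (17 of 25 fell and 2 rose; median -0.83, adjusted p = 0.00513; adjusted p = 0.185 with an estimated correlation) included HNRNPH1 (-2.13 ± 0.13; -1.48 under the scaling nearest 0) and SRSF4 (-2.17 ± 0.14). Among the CCT chaperonin subunits 5 of 7 fell (median -1.12, adjusted p = 0.0375; adjusted p = 0.412 with an estimated correlation), with CCT4 at -1.90 ± 0.16 (-1.32 under the scaling nearest 0). Of 30 genes with symbols of translation initiation factors 16 fell and 4 rose (median -0.52, adjusted p = 0.0375; adjusted p = 0.412 with an estimated correlation). EIF2AK1, EIF2AK2, EIF2AK3, EIF4EBP1, EIF4EBP2 and EIF4ENIF1 among them are kinases or binding proteins and not factors. The medians of these 9 families kept their sign under the 8 scalings. Camera did not call RAB GTPases (3 rose and 9 fell, median -0.53, adjusted p = 0.205). Nor did it call aminoacyl-tRNA synthetases (6 rose and 5 fell, median -0.04, adjusted p = 0.848) or solute carriers (48 rose and 36 fell, median 0.17, adjusted p = 0.488). The last 2 medians changed sign with the scaling.

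Falls in PBMC reached further than rises. The 99th percentile of falls over all tested features was 4.99 on the log2 scale (31.9-fold) and that of rises 3.18 (9.07-fold). A floor of the signal does not account for this, since among the 8440 brightest features the excess was at least 1.769 in each bird. The choice among the 8 scalings tried does not, since the excess was at least 1.298 under each. All of them kept the median difference over all features between -0.304 and 0.239. A larger shift of the zero point, which would change the excess, was not tried. If white cell RNA is diluted by red cell RNA in whole blood, rises on isolation share an upper limit at any level. The 99th percentile of rises differed by 0.319 between 4 equal classes of level (2.69 to 3.01) while that of falls ran from 3.08 to 4.73. These classes hold only the 28354 features above background on all 8 arrays, a filter that itself limits rises and falls of dim features. Dilution therefore stays open, with cell proportions not measured.

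The birds pair the arrays, so the real split was set against the splits that also part all 4 birds. With the real one these are 8 splits, too few for a share under 0.05. The real split gave 26711 features (13413 higher in PBMC and 13298 higher in whole blood), 1 of 8 splits with as many in each case, and the highest of the others gave 0 (2 to 660 at an unadjusted p under 0.05, against 27142). For the 13 lists, 4 of the 8 splits gave as many, and the highest other gave 14. All 34 other splits of the 8 arrays into groups of 4 and 4 mix whole blood and PBMC. They gave 0 features, 6 to 14 lists with 3 arrays of 1 kind in a group, and 1 to 4 lists with 2 of each. Sample type was balanced in the latter, so a list call by camera with its preset correlation need not reflect sample type. The split by slide row gave 0 features and 2 lists. The fit of a mixed split leaves the difference between sample types in the spread within each group, which hides smaller effects. A count of 0 features there therefore cannot exclude an effect of slide row or of the birds.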
